A study of Mus musculus with 30 samples.

How the data were processed

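The deposited data were a table of bulk RNA-seq values per gene for 24 libraries and a table of UMI counts per gene and cell for 6 10x libraries. Bulk RNA was amplified with a SMARTer kit from polyA RNA and sequenced on a HiSeq2000 as paired 50 bp reads, according to the sample records. Per the labels, the 10x libraries aimed at 3000 cells per replicate and 50000 reads per cell, and the replicates of a group came from 3 different mice. Whether one mouse gave cells to several populations is not stated. The submitters' processing notes name Bowtie, TopHat and Cell Ranger 2.2 and the builds mm10 and GRCh37, with no role for each. The version of Bowtie and TopHat, the annotation, the counting tool, its use of strand and its treatment of reads that map to several places are not given in the sources used here. Genes that overlap or share reads with near copies are therefore uncertain.

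The bulk table is named as FPKM, yet it held whole-number counts with totals that differ between libraries, so the deposited bulk values were treated as counts of reads per gene that the authors had not normalized. Of its 24063 gene names, 27 were dates, a trace of spreadsheet conversion, and 4584 genes were at 0 in all libraries. Among 11720 genes with a mean count over 100, 166 had only even counts in all 24 libraries, Myc and Kit among them. Their counting error is larger than the counts imply. The deposited 10x table held counts of UMIs for 27933 genes, and each cell's name gave its library. The 10x totals were 28546967 to 44159208 UMIs. PCR reads without molecular identifiers are not independent molecules, so floors cover counting error only.

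Bulk counts were analysed in R 4.3.3 with edgeR 4.0.16. Limma on log2 FPKM had been planned, and because the table held counts the quasi-likelihood test of edgeR (glmQLFit and glmQLFTest) was used instead, with the planned samples and contrasts. Genes were kept by filterByExpr, libraries scaled by TMM, and 1 mean fitted for each of 8 groups, which left 16 residual degrees of freedom and a spread shared by all groups. Contrasts were Mettl3KO against WT within each population, the difference of that effect between HSC and each MPP population, and WT HSC against each WT MPP population. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast are called changed. A log2 fold change against a group with 0 counts depends on the prior count, so such genes are given as "at least N-fold", computed against a floor of 3 counts over the group. Medians of gene lists are repeated with such members at that bound where this moves them. Coordinates, strands and exon counts are from the GENCODE vM21 annotation of GRCm38, 1-based.

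Cells with over 10% mitochondrial UMIs were removed (297 cells). Log-normalized values of 1999 variable genes, without mitochondrial genes, Xist, Tsix and Mettl3, were reduced to 30 principal components, and cells clustered by Leiden at resolution 1 over 20 neighbours with scanpy 1.11.5, leidenalg 0.10.2 and Python 3.11.15. A cluster was named from 12 marker lists when the best list had a mean log2 fold of at least 1 with at least 3 markers at least 2-fold up, and the 10 leading genes of the cluster held at least 1 of its markers and no more of any other class. Clusters named HSC/MPP and lymphoid-primed were pooled as HSC/MPP-like after the data were seen. Scrublet's automatic threshold marked 150 cells (0.61%) as doublets, and these were kept. UMI counts were summed per library over all LK cells, and over each of the 6 classes with at least 50 cells in every library, and tested with the same edgeR test, TMM and filter. Class shares were tested with edgeR on cell numbers without a trend in the dispersion, adjusted over 10 classes, with an exact two-sided permutation test beside it.

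The 24 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 between genes, two-sided and adjusted over the lists of a population. Lists with fewer than 3 measured members were left out. Each call is repeated with an estimated correlation, under which B cell genes held in MPP1 and erythroid genes in granulocyte progenitor-like cells. Between WT populations, lymphoid genes held in all 3 contrasts, megakaryocyte genes against MPP1 and MPP4, HSC identity, T and NK cell and B cell genes against MPP2 and MPP4, and G1/S genes against MPP2. The lists covered the m6A writer complex, m6A readers and erasers, HSC identity, lymphoid priming, granulocyte and monocyte priming, megakaryocyte priming, erythroid genes, MYC targets, ribosomal proteins, G1/S, G2/M, CDK inhibitors and quiescence, p53 targets, interferon-stimulated genes, RNA sensing, the integrated stress and unfolded protein response, immediate early genes, heat shock, oxidative phosphorylation, and markers of T and NK cells, B cells, macrophages, neutrophils and endothelium. Several genes stand in more than 1 list, such as Cdkn1a and Vwf, and Thy1 and Emcn are also expressed by stem cells.

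Groups, contrasts, gene lists, marker lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named as added. The rule takes Mettl3 and Myc, the 10 largest rises and falls among called genes whose 3 values per group do not overlap (10% of genes by chance) and whose mean reaches 5 CPM in bulk (planned as FPKM) or 20 CPM in 10x sums in the higher group, without names of the Gm, Rik and -ps forms, up to 4 members of each list with the lowest adjusted p, and the 5 largest differences of each sign per interaction. The text may name fewer of the largest changes and list members, taken in order, and some genes are not reported here. The non-overlap condition was not applied to interactions, which compare 4 groups. Genes changed in all 4 populations were listed after their values were seen.

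Alternatives were other normalizations (RLE, quantile normalization, log2 CPM in limma), DESeq2 1.42.0, no filter on low counts, library quality weights (planned with limma's arrayWeights, run with voom), a fit of the compared libraries alone, a replicate block, removal of length and GC trends per library, each library left out in turn, Leiden resolution 2, classes defined on WT cells and removal of the 3% of cells with the highest doublet scores. DESeq2, RLE and log2 CPM for bulk, the length and GC correction, clusters rebuilt without called genes, thinning of cells to 3000 UMIs and removal of mature neutrophil-like cells were added after the data were seen. Thinning left out 59, 0 and 419 WT cells and 18, 10 and 79 Mettl3KO cells. Gene and list calls in 3 contrasts were tested on simulated data, drawn from the libraries' own means and sizes with 200 genes changed. In the HSC contrast (15058 genes) 0% of 1.5-fold, 25.4% of 2-fold and 66.7% of 4-fold changes were recovered, in the LK sums (12743 genes) 56.7%, 79.1% and 95.5%, and in HSC/MPP-like sums (9328 genes) 38.8%, 89.6% and 98.5%, with 4.62% to 4.98% false calls. Figures were drawn with matplotlib 3.10.9.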

Results

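The series examined blood-forming cells from the bone marrow of mice with a floxed Mettl3 gene, with or without the Mx1-Cre transgene. Mettl3 is the catalytic subunit of the nuclear complex that writes m6A, the most frequent internal modification of messenger RNA. Mx1-Cre is switched on by the interferon response to pIpC, a synthetic double-stranded RNA, and per the labels the cells were collected 3 weeks after that treatment. Mice with Cre are called Mettl3KO here and mice without it WT. RNA-seq libraries were made from 4 sorted populations that were negative for lineage markers and positive for Sca1 and c-Kit. They were the HSC (CD150+;CD48-), which holds most long-term stem cells, and the multipotent progenitors MPP1 (CD150-;CD48-), MPP2 (CD150+;CD48+) and MPP4 (CD150-;CD48+). Each population was taken from 3 mice of each genotype, which made 24 bulk libraries. Droplet single-cell RNA-seq (10x Chromium) covered Lin-;c-Kit+ (LK) cells, the wider compartment that also holds myeloid, erythroid and megakaryocytic progenitors, from 3 WT and 3 Mettl3KO mice. Bulk libraries held 28896000 to 55277000 counts, and the 45S ribosomal RNA precursor Rn45s took 1.65% to 5.50% of them. Its share was 5.49%, 5.12% and 5.50% in replicate 2 of the HSC, MPP1 and MPP2 Mettl3KO groups, against at most 3.61% in every other library. The 10x libraries kept 24396 of 24693 cells (WT 4483, 3514 and 4348, Mettl3KO 4239, 2946 and 4866), with medians of 5945 to 10490 UMIs and 1887 to 2718 genes per cell. Fold changes are log2 values of Mettl3KO over WT with their SE unless another pair is named, and levels are CPM (counts scaled to the TMM-adjusted library total) given as mean ± SD over 3 libraries. With 3 mice against 3, no exact two-sided permutation test can give a p below 0.1, so genes are called changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Medians given for a gene list are of log2 fold changes, and p values of lists are from camera.

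The targeted gene was measured first. Mettl3 (GRCm38 chromosome 14, 52294841 to 52305128, minus strand, 11 exons) fell in all 4 sorted populations. In HSC it went from 36.9 ± 5.52 CPM in WT to 14.4 ± 2.78 CPM in Mettl3KO (log2 fold change -1.35 ± 0.18, adjusted p = 1.2e-04). The values were 36.5, 31.5 and 42.5 CPM in the 3 WT libraries and 14.4, 17.2 and 11.6 CPM in the 3 Mettl3KO libraries. The fall was from 34.9 ± 2.89 to 12.4 ± 0.473 CPM in MPP1 (log2 fold change -1.49 ± 0.19, adjusted p = 6.8e-05). It was from 32.5 ± 2.55 to 15.4 ± 2.201 CPM in MPP2 (log2 fold change -1.08 ± 0.18, adjusted p = 0.0030). In MPP4 it was from 32.8 ± 1.405 to 19.2 ± 2.73 CPM (log2 fold change -0.77 ± 0.18, adjusted p = 0.022). All 3 Mettl3KO libraries lay below all 3 WT libraries in each population. The MPP4 call was lost without WT replicates 1 (0.057), 2 (0.089) and 3 (0.072) and Mettl3KO replicates 1 (0.089) and 2 (0.10), the adjusted p of each fit being given in parentheses. The MPP1 call was lost in a fit of the 6 MPP1 libraries alone (adjusted p = 0.068). Summed over all LK cells, Mettl3 fell from 20.3 ± 1.82 to 12.1 ± 1.28 CPM (log2 fold change -0.75 ± 0.10, adjusted p = 0.0012), with 19.7, 22.3 and 18.9 CPM in WT and 10.6, 12.5 and 13.1 CPM in Mettl3KO. The deleted exons are not named in the labels, and a 3' tag outside them would not report the deletion. Myc, which drives growth and ribosome production (chromosome 15, 61985391 to 61990374, plus strand, 3 exons), was fixed as the other gene to report. Its log2 fold change was -0.64 ± 0.20 in HSC (adjusted p = 0.064), -0.17 ± 0.20 in MPP1 (0.64), -0.08 ± 0.20 in MPP2 (0.92) and -0.24 ± 0.20 in MPP4 (0.63), none past the threshold. The HSC change passed with DESeq2, with library quality weights and after removal of length and GC trends. Myc was also one of 166 genes with only even counts in all 24 bulk libraries.

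**Figure D1:**
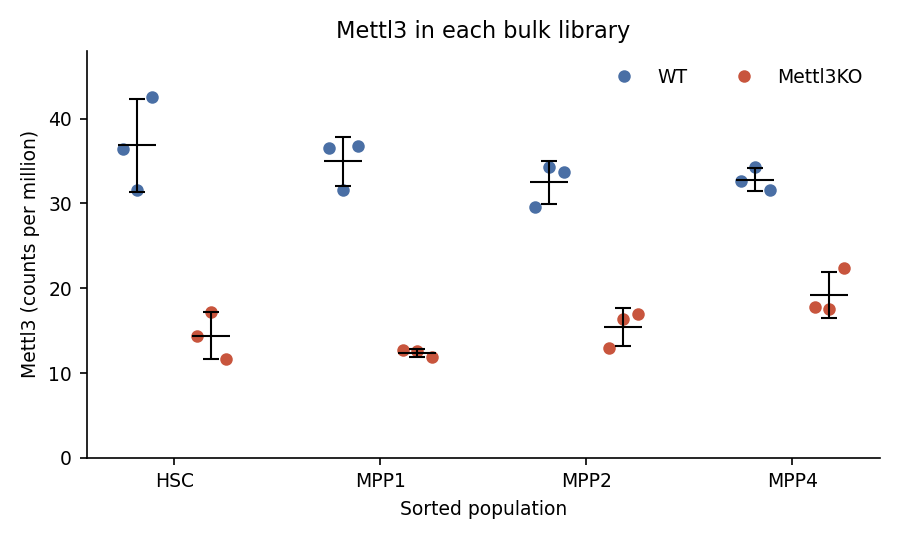
Mettl3 in each bulk library, in CPM on the vertical axis, by sorted population on the horizontal axis; points are libraries, long lines means and error bars SD over 3 libraries. In every population the 3 Mettl3KO libraries lie below the 3 WT libraries.

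The WT libraries show how the populations differ without the deletion. HSC had more RNA of stem cell genes and less of lymphoid, B cell and DNA replication genes than MPP2 and MPP4. Against MPP4, Esam (2.57 ± 0.26), an adhesion molecule of stem cells, Mllt3 (2.13 ± 0.24) and the cell cycle inhibitor Cdkn1c (2.85 ± 0.35) were higher in HSC. Upward, 20 of 25 HSC identity genes passed (median 2.57, adjusted p = 5.9e-20, adjusted p = 0.0016 with an estimated correlation). The platelet adhesion gene Vwf (5.13 ± 0.77) was among 12 of 17 megakaryocyte genes that were higher in HSC (median 2.92, adjusted p = 1.4e-09, adjusted p = 0.031 with an estimated correlation). Il7r, the interleukin 7 receptor of lymphoid progenitors, had no count in HSC and was at least 1071-fold lower than in MPP4. The recombination enzyme gene Dntt differed by -5.23 ± 0.57, and 10 of 15 lymphoid priming genes were lower (median -2.13, adjusted p = 1.3e-13, adjusted p = 0.0016 with an estimated correlation). All 12 B and plasma cell genes were lower in HSC than in MPP4, Cd79a by -8.53 ± 0.41 (median -8.60, adjusted p = 4.7e-24, adjusted p = 1.6e-04 with an estimated correlation). So were 10 of 12 T and NK cell genes (median -8.56, -5.90 at the bound, adjusted p = 8.6e-14, adjusted p = 0.0016 with an estimated correlation) and 15 of 26 G1/S genes (median -0.69, adjusted p = 3.4e-09, adjusted p = 0.081 with an estimated correlation). The HSC against MPP2 contrast ran the same way for HSC identity (14 of 25, Mllt3 2.19 ± 0.24, median 1.59, adjusted p = 2.5e-22, adjusted p = 0.0017 with an estimated correlation). Of 15 lymphoid priming genes 7 were lower, Il7r at least 284-fold (median -1.69, adjusted p = 1.2e-11, adjusted p = 0.0043 with an estimated correlation). B cell genes were lower in 11 of 12 cases (median -6.28, adjusted p = 2.1e-23, adjusted p = 1.9e-04 with an estimated correlation) and G1/S genes in 8 of 26, Fen1 by -0.89 ± 0.13 (median -0.73, adjusted p = 1.6e-13, adjusted p = 0.024 with an estimated correlation). Macrophage genes, foreign to these sorts, were lower in HSC than in MPP2 (1 of 13, all 13 over the list alone, median -5.29, adjusted p = 4.4e-09, adjusted p = 0.18 with an estimated correlation). Cd48, which the gate itself selects, was lower in HSC than in MPP2 (-4.35 ± 0.37) and MPP4 (-4.63 ± 0.38), and Slamf1, which encodes CD150, was higher than in MPP4 (4.63 ± 0.58), which checks the sort labels. HSC and MPP1 differed in 4 genes (1044 at an unadjusted p under 0.05), Slamf1 (3.13 ± 0.54), BC035044 (-2.19 ± 0.33), Lat2 (-1.70 ± 0.25) and Il7r, at 0 in HSC and at least 53.1-fold lower than in MPP1. Yet megakaryocyte genes were higher in HSC than in MPP1 as a set (median 1.60, adjusted p = 5.7e-11, adjusted p = 0.037 with an estimated correlation). Lymphoid genes were lower (median -1.01, adjusted p = 4.1e-09, adjusted p = 0.037 with an estimated correlation). Of 15545 genes, 616 (225 higher, 391 lower) separated HSC from MPP2 and 1877 (844 and 1033) separated it from MPP4. After removal of length and GC trends the MPP4 split was 598 and 1378, with the median of all genes moving from 0.04 to -0.10. DESeq2 called 132 genes for MPP1, 1498 for MPP2 and 2991 for MPP4, quality weights 47, 2066 and 3909. The counts depended on single libraries, with 378, 210, 207, 407, 260 and 361 genes for MPP2 without HSC WT 1, MPP2 WT 1, HSC WT 2, MPP2 WT 2, HSC WT 3 and MPP2 WT 3. They were 738, 676, 1145 and 986 for MPP4 without MPP4 WT 1, HSC WT 2, MPP4 WT 2 and MPP4 WT 3, and 8 and 2 for MPP1 without HSC WT 1 and MPP1 WT 2. For MPP1, Slamf1 was lost without HSC WT replicate 3 (0.31) and MPP1 WT replicates 1 (0.13), 2 (0.19) and 3 (0.10), Lat2 without MPP1 WT replicate 2 (0.056), Il7r with quality weights (0.14), and all 4 in an edgeR fit of the 6 libraries compared (1014 at an unadjusted p under 0.05).

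The main question of the design was what loss of Mettl3 does to HSC. In Mettl3KO HSC, some lymphoid priming genes fell, 2 of 25 HSC identity genes rose and 3 fell, and some p53 targets, MYC targets and m6A readers rose. No list passed with an estimated correlation (adjusted p from 0.34). Hlf, a transcription factor of stem cells (chromosome 11, 90336536 to 90390895, minus strand, 4 exons), fell from 427 ± 64.8 to 113 ± 16.8 CPM (log2 fold change -1.91 ± 0.22, adjusted p = 2.3e-05). Selp, the adhesion molecule P-selectin (chromosome 1, 164115264 to 164150026, plus strand, 16 exons), rose from 64.5 ± 12.1 to 342 ± 33.7 CPM (log2 fold change 2.41 ± 0.29, adjusted p = 4.2e-05). Flt3, a cytokine receptor of multipotent and lymphoid progenitors (chromosome 5, 147330741 to 147400489, minus strand, 24 exons), fell from 150.2 ± 88.0 to 11.02 ± 4.10 CPM (log2 fold change -3.77 ± 0.45, adjusted p = 3.5e-05). Dntt (-3.27 ± 0.53) and Cd34 (-1.25 ± 0.27) fell with it. In all, 6 of 15 lymphoid priming genes fell, 9 adjusted over the list alone (median -0.87, adjusted p = 8.3e-05, adjusted p = 0.34 with an estimated correlation). The cell cycle inhibitor and p53 target Cdkn1a rose from 9.61 ± 2.97 to 65.4 ± 23.2 CPM (2.76 ± 0.36) and Phlda3, a p53-induced repressor of AKT, rose by 2.57 ± 0.33. They were among 4 of 22 p53 targets that rose, 5 adjusted over the list alone, where 1 also fell (median 0.13, adjusted p = 0.041, adjusted p = 0.44 with an estimated correlation). Of 40 MYC targets, 8 rose, 12 adjusted over the list alone with 1 falling (median 0.24, adjusted p = 1.4e-04, adjusted p = 0.44 with an estimated correlation). Leading ones were the nucleolar proteins Ncl (0.99 ± 0.13) and Rrs1 (0.96 ± 0.16) and the DNA repair enzyme Apex1 (1.25 ± 0.24). Fen1, a nuclease of DNA replication, rose (1.17 ± 0.13) as the single passing gene of 26 in G1/S (median 0.18, adjusted p = 0.047, adjusted p = 0.75 with an estimated correlation).

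Within the writer complex, Rbm15, which recruits the complex to RNA (chromosome 3, 107325421 to 107333673, minus strand, 2 exons), rose from 9.63 ± 2.41 to 33.9 ± 9.10 CPM in Mettl3KO HSC (log2 fold change 1.82 ± 0.26, adjusted p = 2.0e-04). Wtap fell (-0.98 ± 0.22, lost without Mettl3KO replicate 2 (0.052)). Of 11 m6A readers and erasers 3 rose and 1 fell. Ythdf2, which directs modified RNA to decay, rose (1.32 ± 0.27), as did the nuclear reader Ythdc1 (0.74 ± 0.17, lost without WT replicate 1 (0.072) and Mettl3KO replicate 2 (0.063)). Erythroid genes were lower as a set, 4 of 20 passing downward and 2 rising and 5 falling adjusted over the list alone (median -0.65, adjusted p = 0.047, adjusted p = 0.75 with an estimated correlation), with Car1 at -4.52 ± 0.70. The granulocyte and monocyte regulator Cebpa fell (-1.95 ± 0.38). The endothelial and stem cell sialomucin Emcn fell (-2.26 ± 0.43). Sets that passed without a member passing edgeR's test were ribosomal proteins (76 genes, median 0.41, adjusted p = 8.3e-05, adjusted p = 0.88 with an estimated correlation, 5 members at an unadjusted p under 0.05 and 0 by DESeq2) and G2/M genes (24 genes, median 0.50, adjusted p = 0.041, adjusted p = 0.88 with an estimated correlation, 4 and 0). Ribosomal protein genes took 2.01%, 1.04% and 2.26% of the counts in WT and 1.41%, 2.79% and 2.55% in Mettl3KO HSC, so the genotypes overlapped and WT replicate 2 was lowest. Heat shock passed as well without a member (10 genes, median 0.63, adjusted p = 0.015, adjusted p = 0.44 with an estimated correlation, 4 and 1). Macrophage genes were lower as a set (13 genes, median -2.97, adjusted p = 0.016, adjusted p = 0.75 with an estimated correlation, 4 at an unadjusted p under 0.05 and 3 by DESeq2). So were endothelial genes (12 genes, median -2.81, -2.15 at the bound, adjusted p = 0.022, adjusted p = 0.56 with an estimated correlation) and immediate early genes (16 genes, median -1.47, adjusted p = 0.0064, adjusted p = 0.75 with an estimated correlation). The remaining lists, namely m6A writers, m6A readers, HSC identity, granulocyte and monocyte priming, megakaryocyte priming, CDK inhibitors, interferon-stimulated genes, RNA sensing, integrated stress, oxidative phosphorylation and genes of T and NK cells, B cells and neutrophils, had camera adjusted p values from 0.107 to 0.980.

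The largest rises in HSC with no overlap between genotypes were Slc6a8 (creatine transporter, 8.39 ± 2.05, lost without WT replicates 1 (0.077) and 2 (0.078)) and the matrix proteoglycan Vcan (7.09 ± 1.81, lost without WT replicates 1 (0.083) and 3 (0.081) and Mettl3KO replicate 2 (0.056)). Next came C2cd4b (chromosome 9, 67759437 to 67760930, plus strand, 2 exons, 6.67 ± 1.26, from 0.339 ± 0.587 to 34.0 ± 24.6 CPM) and Col20a1 (5.88 ± 1.06). The largest falls were Tspan8 and Tlr7, which had no count in the 3 Mettl3KO libraries and were at least 258-fold and 241-fold lower, then Hnf4a (-6.42 ± 0.87) and Adamtsl5 (-5.73 ± 1.15). In total 958 of 15545 genes changed in HSC, 571 up and 387 down, of which 592 moved at least 2-fold. DESeq2 called 1807, library quality weights 2519 and a fit of the 6 HSC libraries alone 518, without Cd34 (adjusted p = 0.055), Rrs1 (0.0503), Cebpa (0.060) and Ythdc1 (0.11) among the genes named. With quality weights Dntt (0.055) and Tlr7 (0.092) did not pass. Leaving out WT replicates 1 or 2 or Mettl3KO replicates 2 or 3 left 621, 557, 518 and 481.

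In MPP1, Hlf, Selp, Cdkn1a and Rbm15 moved in the same direction as in HSC, and B cell and recombinase genes were higher in Mettl3KO. The B cell genes included Cd79a, a chain of the B cell receptor, which rose from 1.90 ± 0.755 to 26.4 ± 3.78 CPM (log2 fold change 3.80 ± 0.33, adjusted p = 7.0e-07). Higher too were the surrogate light chain gene Vpreb1 (3.44 ± 0.48), Vpreb3 (3.38 ± 0.58) and Mzb1 (3.605 ± 0.46). In total 8 of 12 B cell genes rose, 10 adjusted over the list alone (median 3.52, adjusted p = 1.0e-09, adjusted p = 0.021 with an estimated correlation). The recombinase genes Rag1 (4.68 ± 0.70) and Rag2 (3.64 ± 0.68) rose while Flt3 (-2.30 ± 0.42) and Cd34 (-1.37 ± 0.27) fell, so that the lymphoid priming list did not pass (median -0.21, adjusted p = 0.91). T and NK cell genes rose in 4 of 12 cases, 5 adjusted over the list alone, Thy1 by 3.07 ± 0.59 (median 2.41, 2.10 at the bound, adjusted p = 0.0031, adjusted p = 0.32 with an estimated correlation). Hlf fell from 430.1 ± 52.5 to 153 ± 25.4 CPM (log2 fold change -1.49 ± 0.21, adjusted p = 3.2e-04). The 25 HSC identity genes split into 3 that rose and 4 that fell (median 0.19, adjusted p = 0.92). Selp rose from 42.1 ± 4.75 to 383 ± 176 CPM (log2 fold change 3.19 ± 0.30, adjusted p = 2.4e-06). Phlda3 (2.60 ± 0.33) and Cdkn1a (1.76 ± 0.35) rose, 2 of 22 p53 targets (median 0.46, adjusted p = 0.030, adjusted p = 0.31 with an estimated correlation). So did Rbm15 (2.24 ± 0.26), Ythdc1 (0.99 ± 0.17) and Ythdf2 (1.30 ± 0.27), while Wtap (-1.21 ± 0.22) fell. Erythroid genes fell in 3 of 20 cases, 6 adjusted over the list alone, led by Car2 (-1.24 ± 0.21, median -1.12, adjusted p = 0.0011, adjusted p = 0.41 with an estimated correlation). Ribosomal protein genes (2.25% to 2.69% of counts in WT, 1.66%, 1.94% and, in replicate 3, 0.883% in Mettl3KO) were lower as a set with no member passing edgeR's test (median -0.58, adjusted p = 1.0e-09, adjusted p = 0.96 with an estimated correlation, 25 members at an unadjusted p under 0.05 and 4 by DESeq2). Oxidative phosphorylation genes were lower, 3 of 32 passing (median -0.22, adjusted p = 0.0034, adjusted p = 0.96 with an estimated correlation). The leading rise was Cidec, at 0 in WT and at least 352-fold higher in Mettl3KO, and the leading fall was Treml1, a platelet receptor, at 0 in Mettl3KO and at least 268-fold lower. Altogether 1345 genes changed, 738 up and 607 down, 780 of them at least 2-fold. A fit of the 6 MPP1 libraries alone called 35 genes, of those named here Cidec, Rbm15, Hlf, Selp and Cd79a and none of the others. DESeq2 called 2418 and quality weights 868. Counts of 687, 715 and 793 were left without WT replicates 1, 2 and 3. Vpreb3 (adjusted p = 0.074), Mzb1 (0.063), Rag2 (0.082) and Treml1 (0.25) did not pass with quality weights, nor Cidec with DESeq2 (0.058).

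In MPP2, Hlf and Flt3 fell and Selp and Rbm15 rose, and no list passed with an estimated correlation (adjusted p from 0.32). Hlf fell from 161 ± 24.4 to 41.3 ± 8.97 CPM (log2 fold change -1.96 ± 0.22, adjusted p = 6.2e-05) and the adhesion gene Esam rose (1.46 ± 0.25). Flt3 fell from 294 ± 107 to 56.8 ± 19.4 CPM (log2 fold change -2.37 ± 0.42, adjusted p = 0.0043). It was one of 3 of 15 lymphoid priming genes that fell, 5 adjusted over the list alone (median -0.42, adjusted p = 0.0071, adjusted p = 0.52 with an estimated correlation). Selp rose (2.44 ± 0.29), as did the GATA1 cofactor Zfpm1 (1.86 ± 0.33), Rbm15 (1.72 ± 0.26) and Ythdc1 (1.06 ± 0.17). Ncl (0.89 ± 0.13) led 5 of 40 MYC targets that rose, 6 adjusted over the list alone (median 0.25, adjusted p = 1.2e-06, adjusted p = 0.32 with an estimated correlation). Phlda3 (1.88 ± 0.32) led 2 of 22 p53 targets, 3 over the list alone (median 0.31, adjusted p = 0.018, adjusted p = 0.32 with an estimated correlation). Macrophage genes fell in 2 of 13 cases, 7 adjusted over the list alone (median -3.57, adjusted p = 3.2e-05, adjusted p = 0.61 with an estimated correlation). One was the scavenger receptor Cd163, from 122 ± 137 to 11.4 ± 2.30 CPM (-3.43 ± 0.64, lost without WT replicate 1 (0.061)). The other was the secreted macrophage protein Cd5l, from 138 ± 182 to 0.0388 ± 0.0110 CPM (-11.66 ± 2.42, lost without Mettl3KO replicates 1 (0.088), 2 (0.072) and 3 (0.069)). Ribosomal protein genes were higher as a set (median 0.40, adjusted p = 2.8e-05, adjusted p = 0.88 with an estimated correlation, 2.06% to 3.05% of counts against 1.96% to 2.32% in WT, no member by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2). Immediate early genes were lower (median -1.31, adjusted p = 0.0077, adjusted p = 0.78 with an estimated correlation). The leading rises were C2cd4b (9.95 ± 1.60), the scaffold protein Dlg5 (7.48 ± 1.42) and Grrp1 (4.76 ± 0.58). In all 387 genes changed, 235 up and 152 down, 252 at least 2-fold, against 1039 by DESeq2, 1488 with quality weights and 628 (420 up, 208 down) after removal of length and GC trends. Leaving out WT replicates 1, 2 or 3 left 146, 182 and 165, and Mettl3KO replicates 1, 2 or 3 left 123, 221 and 228. Cd163 (adjusted p = 0.11) and Cd5l (0.055) did not pass in a fit of the 6 MPP2 libraries alone, nor Cd5l with quality weights (0.30).

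In MPP4, some HSC identity genes fell and some B cell and G1/S genes rose, and no list passed with an estimated correlation (adjusted p from 0.15). Hlf fell from 156 ± 39.6 to 28.8 ± 5.23 CPM (log2 fold change -2.44 ± 0.22, adjusted p = 6.1e-06). The channel gene Trpc6 (-2.99 ± 0.49) and the homeobox gene Hoxa9 (-1.13 ± 0.20) fell as well. They belonged to 9 of 25 HSC identity genes that fell, 13 adjusted over the list alone (median -0.87, adjusted p = 5.4e-09, adjusted p = 0.15 with an estimated correlation). Vpreb1 rose from 66.4 ± 35.5 to 466 ± 190.4 CPM (log2 fold change 2.81 ± 0.45, adjusted p = 0.0014) and Cd79a from 207 ± 48.6 to 654 ± 289.7 CPM (log2 fold change 1.66 ± 0.29, adjusted p = 0.0030). In all 5 of 12 B cell genes rose, 7 adjusted over the list alone (median 2.08, adjusted p = 8.9e-05, adjusted p = 0.17 with an estimated correlation). Rag1 rose (2.86 ± 0.60, lost without WT replicates 2 (0.065) and 3 (0.081) and Mettl3KO replicate 3 (0.057)). G1/S genes rose in 5 of 26 cases, 10 adjusted over the list alone, Fen1 by 0.72 ± 0.13 (median 0.43, adjusted p = 8.4e-08, adjusted p = 0.17 with an estimated correlation). G2/M genes rose in 1 of 24 (median 0.56, adjusted p = 2.4e-05, adjusted p = 0.72 with an estimated correlation). The transferrin receptor Tfrc (1.59 ± 0.28) led 4 of 40 MYC targets, 6 over the list alone (median 0.25, adjusted p = 1.6e-05, adjusted p = 0.24 with an estimated correlation). In addition 1 of 11 m6A readers and erasers rose, 2 over the list alone (median 0.32, adjusted p = 0.0074, adjusted p = 0.17 with an estimated correlation). Car2 fell (-1.33 ± 0.21), one of 2 of 20 erythroid genes, 3 over the list alone (median -0.63, adjusted p = 0.023, adjusted p = 0.72 with an estimated correlation). Of 16 immediate early genes 2 fell, 8 over the list alone (median -1.78, adjusted p = 1.6e-04, adjusted p = 0.72 with an estimated correlation). In all 498 genes changed, 163 up and 335 down, 345 at least 2-fold. Removal of length and GC trends gave 784 (424 up, 360 down), DESeq2 1134, quality weights 1704 and the 6 MPP4 libraries alone 1028. Leaving out WT replicates 2 or 3 left 178 and 142, and Mettl3KO replicates 1, 2 or 3 left 326, 287 and 161.

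Across the 4 populations, 12 genes rose and 28 fell in every one, against 1194 that rose and 1101 that fell in at least 1 and 21 that rose in one and fell in another. The genes named here were chosen after their values were seen. The 12 risers were B3gnt8, Bcl2l1, C2cd4b, Cdv3, Csf2rb, Fen1, Ncl, Rbm15, Rrs1, Selp, Tnfaip8l1 and Zfp948, among them the survival gene Bcl2l1 and the shared cytokine receptor chain Csf2rb. The fallers included Mettl3, Hlf, Emcn, Ctla2a, Ccl3, Klk8, Serpinf1 and Il15. HSC and MPP1 shared 252 rises and 163 falls where independent lists would share 27.1 and 15.1, and 5 genes went opposite ways. HSC and MPP2 shared 181 and 88 (8.63 and 3.78 by chance) with no gene opposite, and HSC and MPP4 shared 25 and 68 (5.99 and 8.34) with 10 opposite. Tested as interactions, the Mettl3KO effect differed between HSC and MPP1 in 6 genes, between HSC and MPP2 in 1 and between HSC and MPP4 in 252 (153 with the higher effect in HSC, 99 in MPP4). In edgeR 1616, 550 and 2455 genes had an unadjusted p under 0.05, and DESeq2 called 161, 70 and 884. With limma's quality weights the counts were 0, 0 and 1366, with 1771 and 974 genes at an unadjusted p under 0.05 for MPP1 and MPP2. The MPP1 count was 18 without HSC Mettl3KO replicate 1 and 26 without MPP1 Mettl3KO replicate 1, and the MPP2 count 3 and 2 without HSC Mettl3KO replicates 1 and 2. The MPP4 count was 123, 130, 801, 109 and 76 without HSC WT 1, WT 2, Mettl3KO 1, Mettl3KO 2 and Mettl3KO 3, and 159, 114, 87, 155 and 74 without MPP4 WT 1, WT 2, WT 3, Mettl3KO 2 and Mettl3KO 3.

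**Figure D2:**
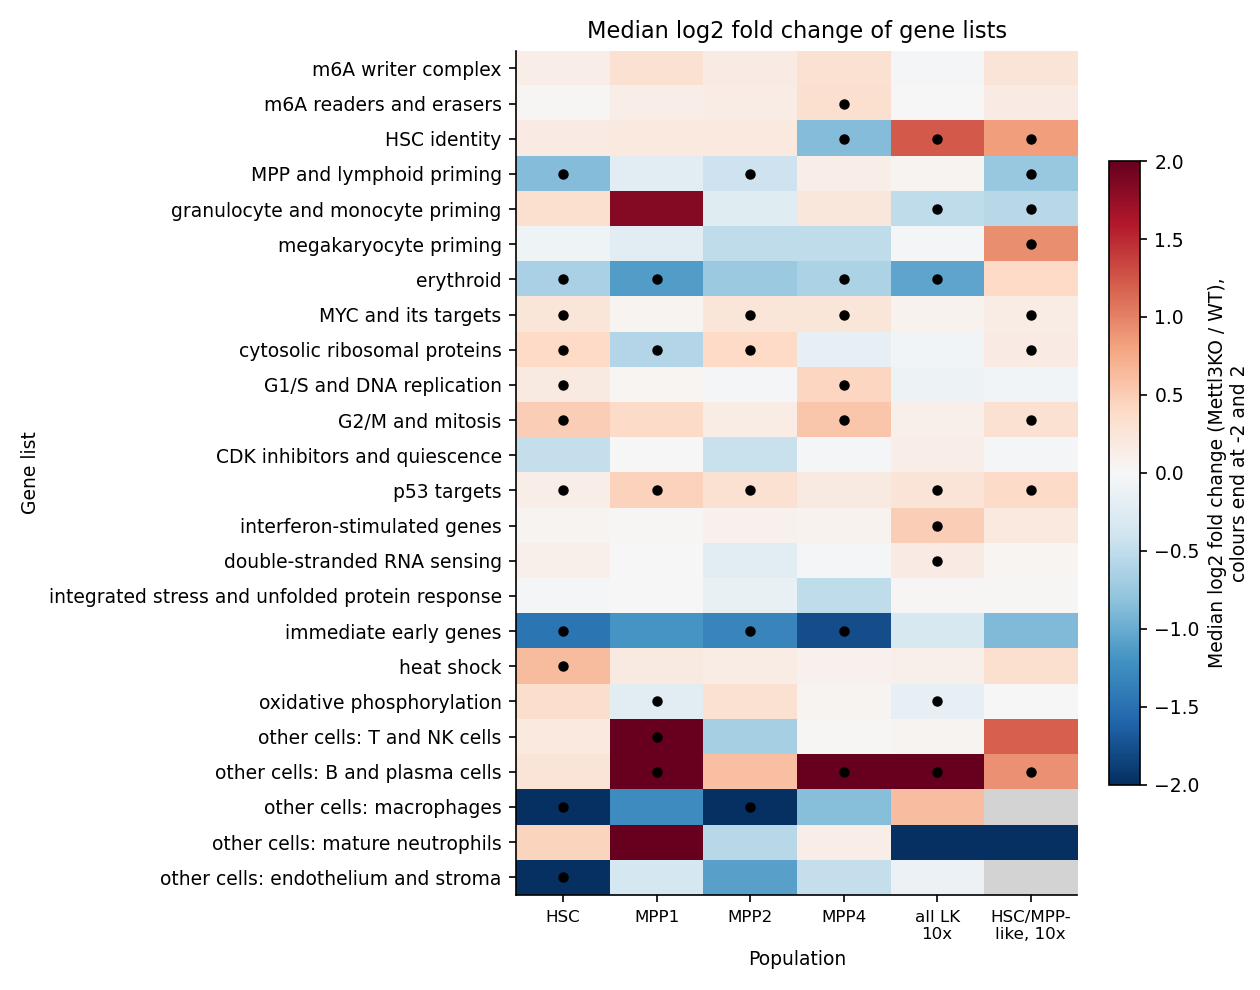
Median log2 fold change (Mettl3KO over WT) of the genes of each list, one list per line and one population per column, from 4 bulk populations, the sum of all LK cells and HSC/MPP-like cells. Dots stand for a camera adjusted p under 0.05 at a preset correlation of 0.01, grey for lists not tested, and colours end at -2 and 2. Lymphoid priming is lower in HSC, MPP2 and HSC/MPP-like cells, and the p53 list is marked in every column except MPP4. With an estimated correlation none of these calls of the 2 lists passed (adjusted p from 0.31 to 0.57).

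The single-cell libraries show which progenitors made up the LK compartment. Clustering gave 23 clusters, of which 18 could be named by marker genes into 10 classes and 5 stayed unnamed. B cell progenitor-like cells were 4.75% ± 1.75 of WT cells and 23.7% ± 6.73 of Mettl3KO cells (ratio 4.98, adjusted p = 0.0064), a share that the sort for lineage-negative cells can set. HSC/MPP-like cells went from 8.80% ± 0.84 to 19.4% ± 5.15 (ratio 2.199, adjusted p = 0.015) and megakaryocyte progenitor-like cells from 4.12% ± 0.55 to 7.33% ± 1.74 (ratio 1.78, adjusted p = 0.040). Erythroid progenitor-like cells fell from 15.7% ± 2.79 to 6.99% ± 2.22 (ratio 0.446, adjusted p = 0.023) and basophil and mast progenitor-like cells from 3.92% ± 0.089 to 1.48% ± 0.50 (ratio 0.377, adjusted p = 0.015). Macrophage-like cells were rare, 5 in WT and 35 in Mettl3KO (ratio 8.04, adjusted p = 0.015). Of these 35, 19 came from Mettl3KO replicate 2, without which the ratio was 4.29. Shares of granulocyte (18.7% and 10.6%, adjusted p = 0.083), monocyte and dendritic (15.8% and 11.9%, 0.185), T and NK (0.424% and 0.337%, 0.514) and mature neutrophil-like cells (8.92% and 1.19%, 0.108) did not pass, and the last were 24.2% of WT replicate 3. In each of the 6 classes that passed, all 3 Mettl3KO libraries lay on one side of all 3 WT libraries, for which the exact two-sided permutation p is 0.1, the smallest possible. Unnamed clusters held 18.9% of WT and 16.9% of Mettl3KO cells. Most HSC/MPP-like cells lay in cluster 3, named by HSC/MPP markers, in Mettl3KO (1942 of its cells against 26 in WT) and in cluster 7, named by lymphoid-primed markers, in WT (1052 against 436). Most megakaryocyte progenitor-like cells lay in cluster 12 in Mettl3KO (855 against 3) and in cluster 16 in WT (501 against 52). With clusters rebuilt without the 3821 genes called in any class, the ratios were 1.99 for HSC/MPP-like and 2.42 for megakaryocyte progenitor-like cells, and with all cells thinned to 3000 UMIs they were 1.35 (adjusted p = 0.145) and 4.20, and 17.1 for macrophage-like cells. Both settings also changed which cells took the HSC/MPP-like and megakaryocyte progenitor-like names. Calls were lost without WT replicate 1 for basophil and mast (adjusted p = 0.0517), erythroid (0.0517), HSC/MPP-like (0.0517) and macrophage-like cells (0.0517), and without Mettl3KO replicate 3 for basophil and mast (0.0521), erythroid (0.0531) and HSC/MPP-like cells (0.0521). The erythroid call was lost without WT replicate 2 (0.0803), and the megakaryocyte call without WT replicates 1 (0.116), 2 (0.107) and 3 (0.0746) and Mettl3KO replicates 1 (0.0903) and 3 (0.124). The granulocyte share passed without WT replicate 3 (0.489, 0.0472) and the neutrophil share without WT replicate 2 (0.0898, 0.0120), while without WT replicate 3 its ratio was 0.939 (0.886).

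**Figure D3:**
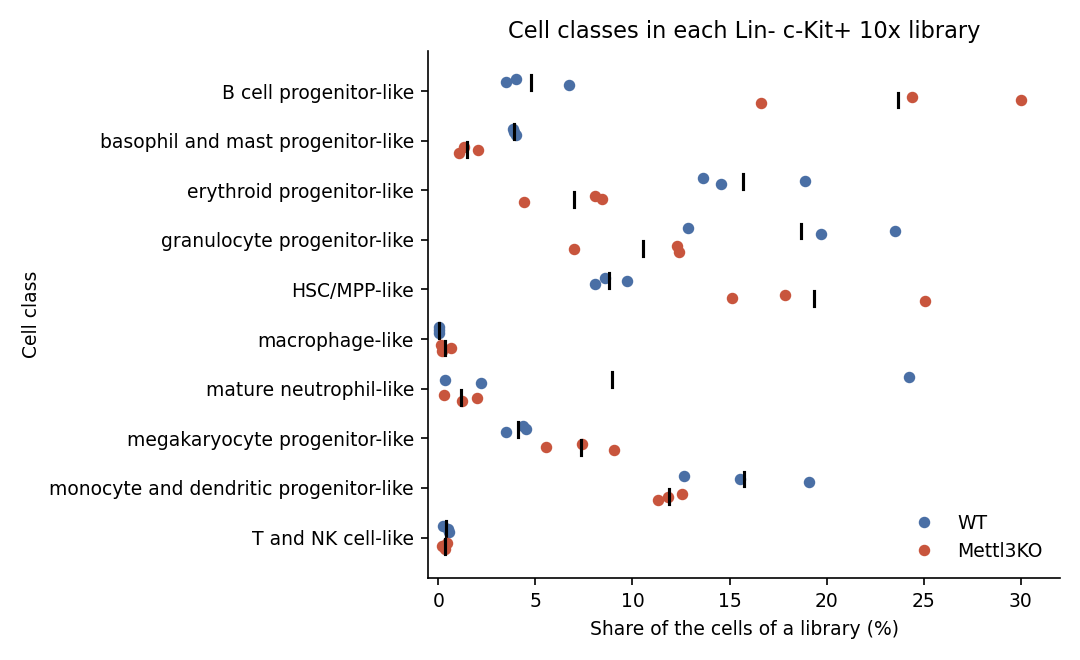
Share of the cells of each 10x library in percent on the horizontal axis, by named cell class on the vertical axis; points are libraries and black lines means over 3 libraries per genotype. The B cell progenitor-like class lies at 16.6% to 30.01% in Mettl3KO and at 3.50% to 6.76% in WT.

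Summed over all LK cells of a library, some stem cell, p53, interferon and B cell genes rose and some erythroid and granulocytic genes fell, alongside the shift in class shares. No list passed with an estimated correlation (adjusted p from 0.37). Of 25 HSC identity genes 17 rose, 19 adjusted over the list alone with 1 falling (median 1.23, adjusted p = 7.2e-08, adjusted p = 0.49 with an estimated correlation). Among them were Gimap6 (log2 fold change 1.65 ± 0.08, adjusted p = 3.8e-05), Gimap1 (2.204 ± 0.12), the protein C receptor Procr (1.89 ± 0.21) and Ctnnal1 (1.68 ± 0.20). Interferon-stimulated genes rose in 20 of 35 cases and fell in 1, 22 and 1 adjusted over the list alone (median 0.49, adjusted p = 7.2e-08, adjusted p = 0.37 with an estimated correlation). Rtp4 rose from 11.2 ± 0.275 to 37.1 ± 4.87 CPM (log2 fold change 1.73 ± 0.10, adjusted p = 4.7e-05), Gbp2 by 1.49 ± 0.13 and Isg15 by 1.28 ± 0.12. Sensors of double-stranded RNA rose in 3 of 16 (median 0.17, adjusted p = 0.028, adjusted p = 0.49 with an estimated correlation), Oasl2 by 0.95 ± 0.15. Among p53 targets 11 of 21 rose (median 0.27, adjusted p = 1.0e-04, adjusted p = 0.37 with an estimated correlation), Phlda3 by 1.41 ± 0.10 and Cdkn1a by 1.52 ± 0.16. Erythroid genes fell in 13 of 19 cases and 1 rose, 14 and 1 over the list alone (median -1.06, adjusted p = 1.9e-07, adjusted p = 0.49 with an estimated correlation). They included the heme enzyme Alas2 (-1.61 ± 0.25), the anion exchanger Slc4a1 (-2.40 ± 0.38) and Car1 (-2.02 ± 0.25). Granule protease Ctsg (-0.50 ± 0.09), the receptor Fcgr3 (-0.68 ± 0.12) and myeloperoxidase Mpo (-0.68 ± 0.13) were among 6 of 18 granulocyte and monocyte genes that fell, 7 over the list alone (median -0.51, adjusted p = 2.6e-05, adjusted p = 0.49 with an estimated correlation). B cell genes rose in 10 of 12 cases (median 2.31, adjusted p = 6.4e-07, adjusted p = 0.49 with an estimated correlation), Fcrla by 1.404 ± 0.21 and Cd79b by 1.53 ± 0.21. In oxidative phosphorylation 5 of 32 genes fell (median -0.16, adjusted p = 1.9e-05, adjusted p = 0.75 with an estimated correlation). Ythdf2 (0.61 ± 0.08) and Ythdc1 (0.41 ± 0.08) rose. Of 10 macrophage genes 3 rose and 3 fell, and the list did not pass (median 0.62, adjusted p = 0.92), with the iron exporter Slc40a1 lower (-1.10 ± 0.16). The complement gene C1qa had the largest rise (4.69 ± 0.81, lost without WT replicates 1 (0.066), 2 (0.079) and 3 (0.081) and Mettl3KO replicate 1 (0.053)). It was followed by the stress protein Nupr1 (3.50 ± 0.21), the cytokine signalling inhibitor Socs2 (3.17 ± 0.22) and the protease inhibitor Serpina3g (2.90 ± 0.17). Altogether 2992 of 13071 genes changed, 1828 up and 1164 down, 1030 at least 2-fold, and 1960 without WT replicate 2.

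Within HSC/MPP-like cells, Mettl3KO cells were mostly of cluster 3, which HSC/MPP markers named, and WT cells mostly of cluster 7, which lymphoid-primed markers named. The changes below, those of stem cell and lymphoid genes above all, therefore include a difference between 2 kinds of cluster. At Leiden resolution 2, 785 WT cells lay in a cluster with HSC/MPP as its best marker list and 308 in a lymphoid-primed one. Hlf fell from 132 ± 10.2 to 37.9 ± 1.85 CPM (log2 fold change -1.79 ± 0.12, adjusted p = 1.0e-09). The stem cell antigen Ly6a (1.25 ± 0.10), Mllt3 (1.55 ± 0.14) and Ltb (1.46 ± 0.12) rose, and in all 12 of 21 HSC identity genes rose and 3 fell (median 0.84, adjusted p = 0.0015, adjusted p = 0.57 with an estimated correlation). Mettl3 fell from 28.0 ± 3.68 to 10.7 ± 1.36 CPM (log2 fold change -1.42 ± 0.19, adjusted p = 1.6e-05) and Myc from 211 ± 23.7 to 157 ± 6.71 CPM (log2 fold change -0.43 ± 0.10, adjusted p = 0.0028). Lymphoid priming fell in 7 of 13 genes (median -0.75, adjusted p = 3.3e-04, adjusted p = 0.57 with an estimated correlation), with Cd34 (-1.07 ± 0.10), the chromatin organiser Satb1 (-1.45 ± 0.19) and Notch1 (-1.17 ± 0.19). Mpo (-1.72 ± 0.12) and Ctsg (-1.15 ± 0.10) fell and Ms4a3 (1.17 ± 0.13) rose within the granulocyte and monocyte list. There 7 of 18 fell and 1 rose, 8 and 1 adjusted over the list alone (median -0.56, adjusted p = 0.017, adjusted p = 0.36 with an estimated correlation). Megakaryocyte genes rose in 6 of 11 cases and fell in 2 (median 0.93, adjusted p = 0.014, adjusted p = 0.57 with an estimated correlation). Selp rose from 18.3 ± 3.25 to 85.4 ± 6.30 CPM (log2 fold change 2.22 ± 0.15, adjusted p = 1.7e-09) and the tetraspanin Cd9 by 0.93 ± 0.13. Rbm15 (0.95 ± 0.15), Ythdf2 (1.14 ± 0.11), Ythdc1 (0.82 ± 0.12) and Ythdf1 (0.65 ± 0.15) rose. MYC targets rose in 9 of 40 cases and fell in 1 (median 0.15, adjusted p = 0.016, adjusted p = 0.35 with an estimated correlation), Apex1 by 0.77 ± 0.10 and Ncl by 0.65 ± 0.09. Ribosomal protein genes rose in 14 of 76 (median 0.17, adjusted p = 3.3e-04, adjusted p = 0.85 with an estimated correlation), Rpl29 by 0.58 ± 0.11. Bax (0.79 ± 0.10), Perp (1.97 ± 0.31) and Phlda3 (1.15 ± 0.19) were among 6 of 15 p53 targets that rose (median 0.39, adjusted p = 0.0021, adjusted p = 0.35 with an estimated correlation). The mitotic genes Birc5 (1.15 ± 0.14) and Mki67 (0.75 ± 0.19) were among 9 of 24 G2/M genes, where 1 fell (median 0.30, adjusted p = 0.025, adjusted p = 0.36 with an estimated correlation). B cell genes were higher as a set with no member passing edgeR's test (8 genes, median 0.92, adjusted p = 0.023, adjusted p = 0.57 with an estimated correlation, 2 at an unadjusted p under 0.05 and 0 by DESeq2). The largest rise was Tnfaip8l1 (4.99 ± 0.41), and the largest falls Klk8 (-2.93 ± 0.16), Serpinf1 (-2.77 ± 0.19) and the chemokine Ccl3 (-2.72 ± 0.18). In all 1915 of 9608 genes changed, 1126 up and 789 down, 501 at least 2-fold, against 1109 with DESeq2, 1173 without Mettl3KO replicate 1 and 1242 without Mettl3KO replicate 3.

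Bulk HSC and 10x HSC/MPP-like cells were then compared gene by gene. Of 9255 genes tested in both, 377 rose and 171 fell in both, where independent lists of these sizes would share 57.0 and 24.1, and no gene called in both went opposite ways. Rbm15 (bulk 1.82, 10x 0.95), Selp (2.41 and 2.22), Ythdf2 (1.32 and 1.14), Hlf (-1.91 and -1.79) and Mettl3 (-1.35 and -1.42) were among the 548 shared genes. Taking the sign alone, 769 genes called in bulk HSC moved the same way in the 10x cells and 18 the other way. Spearman's correlation of the log2 fold changes across genes was 0.65, where genes are not independent replicates.

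**Figure D4:**
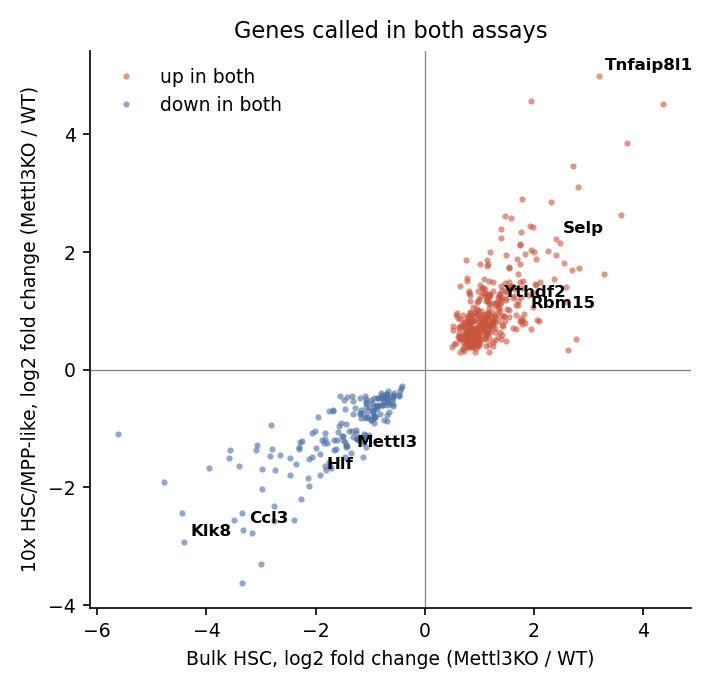
Log2 fold change (Mettl3KO over WT) in bulk HSC on the horizontal axis and in 10x HSC/MPP-like cells on the vertical axis for the 548 genes called in both assays, one point per gene. The 377 genes up in both lie in the upper right and the 171 genes down in both in the lower left.

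Megakaryocyte progenitor-like cells lay mostly in cluster 12 in Mettl3KO and 16 in WT. Pf4, Gp1bb and Serpine2 were leading genes of cluster 16, and Gp5 of cluster 12. The changes below therefore include a difference between 2 clusters. Part of the genes of several lists changed in them, and no list passed with an estimated correlation (adjusted p from 0.37). Platelet factor Pf4 fell from 6914 ± 1165 to 1145 ± 213 CPM (log2 fold change -2.60 ± 0.14, adjusted p = 3.0e-15). The glycoprotein Gp1bb fell from 366 ± 63.9 to 48.3 ± 5.55 CPM (log2 fold change -2.94 ± 0.13, adjusted p = 8.8e-18), while Gp5 rose (1.36 ± 0.11). They belonged to 9 of 15 megakaryocyte genes that fell and 3 that rose, 11 and 3 adjusted over the list alone (median -0.75, adjusted p = 0.0030, adjusted p = 0.64 with an estimated correlation). G2/M genes fell in 17 of 24 cases (median -0.83, adjusted p = 7.2e-08, adjusted p = 0.37 with an estimated correlation), Nusap1 by -1.54 ± 0.16 and Cdca8 by -1.09 ± 0.13. Cdkn1a rose from 8.39 ± 1.02 to 68.4 ± 10.7 CPM (log2 fold change 3.05 ± 0.22, adjusted p = 4.2e-13) and Phlda3 by 3.22 ± 0.27. In all 8 of 11 p53 targets rose, 9 over the list alone (median 0.73, adjusted p = 2.8e-04, adjusted p = 0.37 with an estimated correlation). Interferon-stimulated genes rose in 12 of 22 cases and fell in 1 (median 0.56, adjusted p = 0.0047, adjusted p = 0.37 with an estimated correlation), led by the GTPases Igtp (2.13 ± 0.22) and Irgm1 (1.81 ± 0.21). Ribosomal protein genes rose in 28 of 76 cases, 30 over the list alone (median 0.24, adjusted p = 1.6e-04, adjusted p = 0.68 with an estimated correlation). Chaperones of the endoplasmic reticulum, Sdf2l1 (-0.98 ± 0.11) and Hsp90b1 (-0.86 ± 0.11), were among 9 of 16 stress response genes that fell, where 1 rose (median -0.53, adjusted p = 0.0055, adjusted p = 0.64 with an estimated correlation). Of 18 HSC identity genes 9 rose, Gimap1 by 1.66 ± 0.11 and Esam by 1.56 ± 0.16, and 3 fell, 10 and 3 over the list alone (median 0.62, adjusted p = 0.018, adjusted p = 0.43 with an estimated correlation). B cell genes rose in 3 of 8 cases, 5 over the list alone, Vpreb1 by 1.09 ± 0.25 (median 0.80, adjusted p = 0.041, adjusted p = 0.43 with an estimated correlation). The imprinted gene Dlk1 was at 0 in WT and at least 23.7-fold higher in Mettl3KO, Id1 (5.91 ± 0.46) and the Notch target Hes1 (4.64 ± 0.36) rose, and Serpine2 (-4.30 ± 0.34) fell most. In all 2516 of 7924 genes changed, 1403 up and 1113 down, 697 at least 2-fold, and DESeq2 called 1508.

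In erythroid progenitor-like cells some erythroid genes fell and some MYC targets rose, and no list passed with an estimated correlation (adjusted p from 0.35). Car1 fell from 2739.5 ± 581 to 1275 ± 18.4 CPM (log2 fold change -1.10 ± 0.12, adjusted p = 1.3e-04) and Slc4a1 by -1.401 ± 0.28. They were among 5 of 19 erythroid genes that fell, 9 adjusted over the list alone (median -0.29, adjusted p = 1.6e-05, adjusted p = 0.35 with an estimated correlation). The spermidine synthase gene Srm (0.51 ± 0.07) and lactate dehydrogenase Ldha (0.44 ± 0.08) were among 15 of 40 MYC targets that rose, 23 over the list alone (median 0.26, adjusted p = 7.7e-10, adjusted p = 0.35 with an estimated correlation). Interferon-stimulated genes rose in 11 of 32 cases, 14 over the list alone (median 0.55, adjusted p = 9.4e-08, adjusted p = 0.47 with an estimated correlation), Ifi27l2a by 2.32 ± 0.32. B cell genes, foreign to this lineage, rose in 7 of 9 cases, 8 over the list alone, Igll1 from 9.96 ± 1.82 to 33.8 ± 6.72 CPM (median 1.75, adjusted p = 9.0e-10, adjusted p = 0.35 with an estimated correlation). The Igll1 call was lost with classes defined on WT cells (0.31). Free RNA in the droplets was not measured or removed. Mettl3 itself fell from 28.7 ± 2.35 to 21.6 ± 2.39 CPM (log2 fold change -0.40 ± 0.11, adjusted p = 0.039, lost without WT replicates 1 (0.066) and 2 (0.17) and Mettl3KO replicates 1 (0.16) and 2 (0.16), with DESeq2 and with classes defined on WT cells). The count was 718 of 9872 genes, 430 up and 288 down, 472 with DESeq2, 209 with classes defined on WT cells, and 363, 265 and 357 without WT replicate 2 and Mettl3KO replicates 1 and 2.

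In the other classes fewer genes changed, and Mettl3 did not pass in granulocyte (-0.65 ± 0.17, adjusted p = 0.076), monocyte and dendritic (-0.57 ± 0.15, 0.060) or B cell progenitor-like cells (-0.34 ± 0.22, 0.71). In granulocyte progenitor-like cells Serpina3g rose (1.497 ± 0.13). Erythroid genes fell there in 6 of 13 cases, 9 over the list alone (median -0.92, adjusted p = 7.9e-11, adjusted p = 0.040 with an estimated correlation). B cell genes rose in 6 of 8 (median 1.18, adjusted p = 4.5e-08, adjusted p = 0.26 with an estimated correlation), Cd79a by 1.64 ± 0.23. Tfrc (1.09 ± 0.13) led 4 of 40 MYC targets that rose there, 24 over the list alone (median 0.30, adjusted p = 2.5e-13, adjusted p = 0.37 with an estimated correlation). Monocyte and dendritic progenitor-like cells gained Serpina3g (2.25 ± 0.13) and Gimap6 (2.27 ± 0.25) and lost the growth factor Nrg1 (-1.90 ± 0.14). Among their interferon-stimulated genes 6 of 32 rose, 9 over the list alone (median 0.40, adjusted p = 8.2e-09, adjusted p = 0.15 with an estimated correlation), Psmb9 by 0.43 ± 0.07. Of 8 B cell genes 1 rose, Mzb1 by 2.35 ± 0.22, 6 over the list alone (median 1.90, adjusted p = 2.5e-09, adjusted p = 0.15 with an estimated correlation). In B cell progenitor-like cells 3 of 16 granulocyte and monocyte genes fell, 13 over the list alone (median -1.06, adjusted p = 6.7e-14, adjusted p = 0.28 with an estimated correlation), Hp by -1.34 ± 0.16 and Fcgr3 by -1.29 ± 0.20. There too 5 of 30 interferon-stimulated genes rose, 15 over the list alone (median 0.46, adjusted p = 2.7e-11, adjusted p = 0.28 with an estimated correlation), Ifi27l2a by 0.61 ± 0.10 (lost without WT replicate 2 (0.060)). Erythroid and B cell genes in granulocyte cells, B cell genes in erythroid, monocyte, megakaryocyte and HSC/MPP-like cells and granulocyte genes in B cell progenitor-like cells moved as the shares of their own classes did, so free RNA is not excluded. The counts were 80 of 9806 genes (49 up, 31 down) in granulocyte, 144 of 10106 (104 and 40) in monocyte and dendritic and 31 of 9389 (17 and 14) in B cell progenitor-like cells. Without a filter on low counts they were 462, 404 and 118, without WT replicate 2 they were 21, 88 and 16. Further, 37 and 23 granulocyte genes were left without WT replicate 3 and Mettl3KO replicate 3, 86 monocyte and dendritic genes and 20 B cell genes without Mettl3KO replicate 2.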

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

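The tests of class assignment, of the gate and of B cell progenitors in the MPP1 sort, and the counts over other splits of the bulk libraries, were chosen only after the results were seen. Interaction tests picked out genes whose Mettl3KO effect differed between HSC and another population, 6 against MPP1, 1 against MPP2 and 252 against MPP4 by edgeR. Their values here are log2 differences, the effect in HSC minus the effect in the other population, and fitted differences of genes with no count in a group depend on the prior count. Against MPP1, Vpreb1 differed by -4.90 ± 0.71 (adjusted p = 0.0058), with 0.378 CPM in Mettl3KO and 1.07 CPM in WT HSC against 18.5 and 1.72 CPM in MPP1. Blnk, an adaptor of the B cell receptor, differed by -4.24 ± 0.57 (adjusted p = 0.0043), lower in Mettl3KO HSC and higher in Mettl3KO MPP1. Cd79a differed by -2.67 ± 0.47 (adjusted p = 0.030, lost without HSC WT replicates 1 (0.15) and 2 (0.093), MPP1 WT replicates 1 (0.11) and 3 (0.10), HSC Mettl3KO replicates 1 (0.054), 2 (0.057) and 3 (0.074) and MPP1 Mettl3KO replicate 3 (0.068)). None of these passed with quality weights (adjusted p from 0.37 to 0.52) or in a fit of the compared libraries alone (0.82). Gcsam, a signalling gene of germinal centres, had no count in Mettl3KO HSC and 4.35 CPM in WT HSC, against 10.2 and 13.9 CPM in MPP2 and 12.9 and 16.8 CPM in MPP4. Its difference was -9.999 ± 1.11 against MPP2 (adjusted p = 0.0012, 0.40 with quality weights and 0.057 in a fit of the compared libraries alone) and -10.07 ± 1.11 against MPP4 (5.5e-04).

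Against MPP4, Vcan differed by 9.40 ± 2.29 (adjusted p = 0.041, 0.088 in a fit of the compared libraries alone, lost without HSC WT replicates 1 (0.10) and 3 (0.085), MPP4 WT replicates 2 (0.060) and 3 (0.15), HSC Mettl3KO replicates 2 (0.092) and 3 (0.078) and MPP4 Mettl3KO replicates 1 (0.072), 2 (0.063) and 3 (0.11)). Batf3, with no count in WT HSC, differed by 9.29 ± 2.02 (0.025, 0.099 after quantile normalization and 0.053 on log2 CPM, lost without HSC WT replicates 1 (0.070) and 2 (0.067), MPP4 WT replicates 2 (0.0504) and 3 (0.064), HSC Mettl3KO replicates 2 (0.064) and 3 (0.063) and MPP4 Mettl3KO replicates 2 (0.059) and 3 (0.078)). Fam181b, which fell in MPP4, differed by 5.76 ± 1.05 (0.0083), and Snx31 by 4.24 ± 0.98 (0.030, lost without HSC WT replicates 1 (0.054), 2 (0.083) and 3 (0.067), MPP4 WT replicates 2 (0.054) and 3 (0.090), HSC Mettl3KO replicates 2 (0.090) and 3 (0.072) and MPP4 Mettl3KO replicates 1 (0.058) and 2 (0.079)). Prex2 differed by 4.03 ± 0.91 (0.027, 0.064 in a fit of the compared libraries alone, lost without HSC WT replicates 1 (0.084) and 2 (0.068), MPP4 WT replicates 2 (0.064) and 3 (0.076), HSC Mettl3KO replicate 2 (0.071) and MPP4 Mettl3KO replicates 2 (0.065) and 3 (0.10)). Tspan8 and Fcrl1 had no count in Mettl3KO HSC. Tspan8 differed by -10.66 ± 2.48 (0.035, lost without HSC WT replicates 1 (0.052), 2 (0.062) and 3 (0.063), MPP4 WT replicates 1 (0.074) and 3 (0.0998), HSC Mettl3KO replicates 2 (0.091) and 3 (0.098) and MPP4 Mettl3KO replicates 2 (0.063) and 3 (0.084)). Fcrl1 differed by -9.51 ± 2.34 (0.046, from 0.065 to 0.12 without a filter, in limma and with quality weights, lost without HSC WT replicates 1 (0.12) and 2 (0.065), MPP4 WT replicates 1 (0.087), 2 (0.092) and 3 (0.10), HSC Mettl3KO replicates 1 (0.055), 2 (0.12) and 3 (0.12) and MPP4 Mettl3KO replicates 1 (0.053), 2 (0.076) and 3 (0.096)). Cd6 differed by -7.48 ± 1.76 (0.034, lost without HSC WT replicate 1 (0.0997), MPP4 WT replicates 1 (0.074), 2 (0.064) and 3 (0.099), HSC Mettl3KO replicates 2 (0.10) and 3 (0.053) and MPP4 Mettl3KO replicates 2 (0.077) and 3 (0.062)). Emp1, at 0.201 CPM in Mettl3KO and 8.94 CPM in WT HSC against 136.8 and 42.7 CPM in MPP4, differed by -7.30 ± 0.96 (0.0011).

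A cluster outside the named classes held 888 Mettl3KO cells and 1 WT cell, a mean of 7.36% of Mettl3KO cells (5.98% to 9.51% per library) against 0.00744% of WT cells, with Serpina3g, Fam212a, Gng11, Muc13 and Rab38 as its leading genes.

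Genes with long exons were higher in Mettl3KO bulk libraries of HSC, MPP1 and MPP2. Between the 3441 protein-coding genes with the longest mean exon (over 568 bp) and the 3441 with the shortest (under 202 bp), the median log2 fold change differed by 0.09 in HSC, 0.16 in MPP1, 0.07 in MPP2 and 0.02 in MPP4, with libraries of both genotypes overlapping. With each library's length and GC trend removed it was 0.17, 0.13, 0.11 and -0.08. Mettl3KO then lay above all WT libraries in the first 3 and below them in MPP4. This separation came with the correction, so such a trend stays open. The 10x sums of HSC/MPP-like cells, which start at polyA tails, gave 0.109 (Mettl3KO 0.03 to 0.15, WT -0.01 to 0.01), and megakaryocyte progenitor-like cells gave 0.24. In both, genotypes lay mostly in different clusters, which could give such values. Genomic DNA or unspliced RNA in the bulk libraries is not excluded. Because m6A lies mostly in long exons, loss of Mettl3 is a candidate explanation (smaller of the bulk and 10x values 0.109), but m6A was not measured, MPP4 gave -0.08 after the correction, and the erythroid, granulocyte, monocyte and B cell classes lay between -0.04 and -0.01.

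HSC/MPP-like and megakaryocyte progenitor-like cells took larger shares of Mettl3KO LK libraries. Genes that the knockout changed could shift the class assignment. The ratio of mean shares was at least 1.99 for both classes with clusters built without called genes and with classes defined on WT cells. Pf4 and Gp5, both called, still led the rebuilt megakaryocyte cluster, so such a shift is not excluded. Loss of other cells from the gate would raise the shares of the cells left by the same factor. The share ratio of HSC/MPP-like cells was 1.23 times that of megakaryocyte progenitor-like cells (HSC/MPP-like over megakaryocyte cells 2.42 to 2.78 in Mettl3KO and 1.96 to 2.33 in WT libraries), too small a difference to decide. B cell progenitor-like cells had a share ratio 2.26 times that of HSC/MPP-like and 2.79 times that of megakaryocyte progenitor-like cells, which goes against a common factor, yet the libraries overlapped (B cell over HSC/MPP-like 0.66 to 1.99 in Mettl3KO and 0.36 to 0.83 in WT, over megakaryocyte 1.84 to 5.39 and 0.78 to 1.94). A gain of these cells and a loss of others cannot be told apart. With all cells thinned to the same depth the megakaryocyte ratio was 4.20 and the HSC/MPP-like ratio 1.35 (adjusted p = 0.145). Thinning changed which cells took both names, so these ratios cannot decide on depth. Loss of Mettl3 stays open as a biological explanation, since shares carry no absolute cell numbers.

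B lineage genes were higher in Mettl3KO MPP1, with a median log2 fold change of 3.41 over 8 markers fixed before the test. It stayed between 3.40 and 3.48 without each Mettl3KO MPP1 library, so 1 library alone is excluded. B cell progenitors within the sort would add a common share of their own level. Set against WT 10x B cell progenitor-like cells, the gain was 0.477% for Vpreb3, 0.765% for Ebf1, 0.822% for Vpreb1 and 1.08% for Igll1, 2.27 times between lowest and highest, and Cd79b did not rise by more than 1 (0.24), as the other 7 did. Expression within MPP1 cells predicts the same rises, so the 2 cannot be told apart.

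Each comparison of 3 libraries with 3 allows 10 splits, the real one counted as 1, which are too few for a share under 0.05. The real split called 958 genes in HSC, 1345 in MPP1, 387 in MPP2 and 498 in MPP4, and the highest other split 1, 6, 0 and 0. Between WT populations it called 4, 616 and 1877 genes against at most 1, 0 and 0. For LK, HSC/MPP-like, megakaryocyte, erythroid, granulocyte, monocyte and dendritic, and B cell progenitor-like cells it called 2992, 1915, 2516, 718, 80, 144 and 31, against at most 0, 0, 0, 0, 1, 1 and 3. Of 200 signed splits per interaction 25 were drawn. As many genes as the real one were called by 4 for MPP1 (real 6, highest other 830). The number was 3 for MPP2 (real 1, highest other 180) and 1 for MPP4 (real 252, highest other 197). Splits mixing the genotypes add their difference to the spread, so no share excludes chance. WT libraries of 1 number in HSC and MPP4 correlated (0.09 to 0.14), so may not be independent. Without 1 library the MPP4 count was 74 to 159 in 9 of 12 fits and 216 to 801 in the others. The highest other splits for MPP2 and MPP4, and one with 428 for MPP1, kept the genotypes apart in HSC and so carry their difference. Those with 830 and 199 for MPP1 kept them apart in neither population, which points to a structure among these libraries that was not identified.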

How the results depend on the processing

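The alternatives named above as added were chosen only after the data were seen. RLE size factors, doublet removal, Leiden resolution 2, clusters rebuilt without called genes and removal of neutrophil-like cells left each count recomputed under them within 1.5 times its reported value and each share ratio called in its direction. Without neutrophil-like cells the granulocyte progenitor-like share passed too (ratio 0.527, adjusted p = 0.0062), and calls in bulk HSC with the sign alone in 10x gave 769 shared genes. Other settings moved counts as follows, and the cause was not tested unless given.

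Quality weights in limma voom called 2519, 868, 1488 and 1704 genes in HSC, MPP1, MPP2 and MPP4, 0, 0 and 1366 in the interactions of HSC with MPP1, MPP2 and MPP4 (1771 and 974 at an unadjusted p under 0.05 for the first pair), and 47, 2066 and 3909 between WT HSC and these populations. DESeq2 called 1807, 2418, 1039 and 1134, then 161, 70 and 884, and 132, 1498 and 2991, and in 10x 1109 genes in HSC/MPP-like, 472 in erythroid and 1508 in megakaryocyte progenitor-like cells. A fit of the compared libraries alone, with fewer libraries to estimate the spread, called 518 in HSC, 35 in MPP1, 1028 in MPP4, 0, 0 and 161 in the interactions (790 and 604 at an unadjusted p under 0.05 for MPP1 and MPP2) and 0 and 1093 between WT HSC and MPP1 or MPP2 (1014 for MPP1). Removal of length and GC trends gave 628 in MPP2, 784 in MPP4, 10 in the MPP1 interaction and 8 between WT HSC and MPP1. Quantile normalization gave 11 in the MPP1 interaction and 25 and 945 between WT HSC and MPP1 or MPP2, and log2 CPM in limma 13, 25 and 929. Without a filter on low counts the B cell, granulocyte, and monocyte and dendritic classes had 118, 462 and 404 genes, and with classes defined on WT cells B cell, erythroid and granulocyte had 50, 209 and 170.

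The sources give replicate numbers without saying that a number stands for 1 mouse. Residuals of Mettl3KO and WT libraries of 1 number correlated at -0.14 to 0.05 in bulk and -0.30 to 0.08 in 10x, so the numbers did not pair the genotypes. Between populations, the WT HSC library of the same number matched best in 9 of 9 cases (0.06 to 0.14) and the Mettl3KO HSC library in 3 of 9 (-0.09 to 0.23), so shared mice stay open. A replicate block in a fit of the compared libraries, which takes degrees of freedom, called 30 genes in HSC, 0 in MPP1 (1557 at an unadjusted p under 0.05), 44 in MPP4 and 1, 0 and 31 in the interactions (535 at an unadjusted p under 0.05 for MPP2). Between WT HSC and MPP1, MPP2 and MPP4 it called 14, 1113 and 3603, against 0, 1093 and 2629 in the same libraries without the block. Degrees of freedom alone do not account for those rises. With the block 3 shares passed, and erythroid (ratio 0.446, adjusted p = 0.082), HSC/MPP-like (2.199, 0.094) and megakaryocyte progenitor-like cells (1.78, 0.21) did not. Thinning gave a ratio of 1.35 for HSC/MPP-like cells (adjusted p = 0.145). With an estimated correlation 0, 1, 0 and 0 lists were called in HSC, MPP1, MPP2 and MPP4 and 0 in HSC/MPP-like cells, against 11, 6, 6, 8 and 9, and fry called 4 in HSC, 3 in MPP2 and 5 in MPP4.

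Leaving out 1 library at a time, so that an arm held 2, gave 481 to 1322 genes in HSC, 687 to 1797 in MPP1, 123 to 228 in MPP2 and 142 to 357 in MPP4, 4 to 26, 1 to 3 and 74 to 801 in the interactions, and 2 to 8, 207 to 407 and 676 to 1359 between WT HSC and MPP1, MPP2 and MPP4. In 10x it gave 1960 to 2652 for LK, 16 to 41 for B cell, 1173 to 2440 for HSC/MPP-like, 265 to 729 for erythroid, 21 to 79 for granulocyte, 1931 to 2450 for megakaryocyte and 86 to 201 for monocyte and dendritic cells. From 1 to 6 shares passed, with ratios of 4.31 to 6.31 for B cell, 0.306 to 0.428 for basophil and mast, 0.400 to 0.528 for erythroid, 1.87 to 2.44 for HSC/MPP-like, 4.29 to 10.3 for macrophage-like and 1.58 to 2.00 for megakaryocyte progenitor-like cells. For 802 gene results within the rule for named genes, 5308 of 5845 called values held their direction and call under the other alternatives and 537 lost the call, and 3690 of 4778 held and 1088 lost it without 1 library, with 0 reversed. A pseudocount of 0.1 FPKM was not run, because the table held counts. In simulated data neither HSC/MPP-like nor LK sums recovered more changes at every size. What depth limits was not separated from the spread between libraries.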

Other observations

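The values of this part were looked up after the clusters were seen, and no difference in them was tested. Of the 5 clusters that marker genes could not name, 4 held at least 48 cells of each genotype. Cluster 5 took 9.48% ± 1.90 of WT and 5.97% ± 0.230 of Mettl3KO cells, and cluster 9 took 6.34% ± 0.289 and 1.69% ± 0.775. Cluster 17 took 2.64% ± 0.991 and 1.28% ± 0.167, and cluster 19 took 0.402% ± 0.195 and 0.559% ± 0.225. In clusters 9 and 17 all 3 Mettl3KO libraries lay below all 3 WT libraries, as they did in cluster 5.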
